A study of Oryza sativa with 10 samples.

How the data were processed

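Poly(A) RNA of rice (Oryza sativa) cultivar Nijinokirameki was sequenced from directional libraries, per the labels' protocols. Samples came from 2 tissues, endosperm and flag leaf, at day 5 after flowering in 2024. Plants grew under chemical fertilizer (CF, with N, PO4 and K at 56, 176 and 56 kg/ha) or under green manure (GM), hairy vetch plowed into the soil with no chemical fertilizer. Spikelets of a single plant made up each endosperm replicate, and the endosperm was dissected from the embryo while frozen, per the labels. The labels do not state whether leaf replicates came from separate plants or whether either fertilizer regime was repeated over several plots.

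The deposited values are raw counts of unique exon reads per gene, per the labels' file descriptions, in a table of 37727 loci for each tissue. The genome build was IRGSP-1.0, per the submitters' processing notes. The aligner, the counting tool and any read filter are not given in the sources used here. Gene symbols, descriptions and term annotations were taken from the deposited tables themselves, which give a symbol for 13056 loci. No coordinates are given, because the reference gene table at hand is of another assembly. Reads that match several near-identical copies are absent from unique counts, so levels of histones, ribosomal proteins, clustered small heat shock proteins and prolamins carry that uncertainty.

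Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Each tissue was fitted alone: genes passed filterByExpr by group (minimum count 10), libraries were scaled by trimmed mean of M values (TMM), and GM was compared with CF by edgeR's robust quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. A fit of all 10 libraries tested whether the GM effect differed between tissues, as the endosperm effect minus the leaf effect, and compared the tissues under CF. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Levels are TMM-scaled CPM, given as mean ± SD over the libraries of a group.

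A total of 28 gene lists were written before the data were examined, as were the comparisons, the tests and the rule for naming genes. The wording of the list patterns was adapted to the annotation before any comparison was computed. Lists with at least 4 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation and with fry, which asks whether a list's genes move on balance in a single direction. The genes of a list were also adjusted over the list alone.

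The rule named, per tissue, up to 8 called genes with the largest rise and 8 with the largest fall, with a mean of at least 5 CPM, no overlap between groups and an informative name. It also named up to 3 members of smallest p per described list, 7 starch and heat genes in the endosperm, and the 5 largest interactions in each direction. Which lists are described with examples was decided after the list results were seen.

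An exploratory fit of the real counts was run before the test described here was written. The procedure was tested on simulated counts with 200 changed genes, 50 at each log2 change of −2, −1, 1 and 2. For the endosperm (23183 simulated genes tested) it recovered 50, 39, 44 and 50 of these, with 3 false calls among 186. For the flag leaf (20202 genes) it recovered 50, 46, 47 and 50, with 12 false calls among 205. For the difference between tissues (25023 genes) it recovered 49, 38, 44 and 50, with 6 false calls among 187. All simulated genes had the same dispersion and varied independently, with no outlying library. These counts therefore hold for such data and do not give the error rate in the real libraries.

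Alternatives planned before the data were examined were relative log expression (RLE) and upper-quartile scaling, no filter or a stricter filter of 5 CPM, DESeq2, limma-voom, and a fit of both tissues together. The others were a test against a 1.5-fold change, the replicate number as a block, the 20 most abundant genes and the storage proteins left out, and each library left out in turn. An equal-depth alternative for the leaf, the overlap of calls between tissues and the tests of annotation terms were added after seeing the data. The overlap was tested with a 2-sided and each term with a 1-sided Fisher's exact test, against the genes that could have been called. These tests count genes as independent, so their p-values do not measure the spread between libraries. Other groupings of the 6 leaf libraries, 3 against 3, were also fitted, and camera passed some lists in each of them.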

Results

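The data are gene-level read counts from 10 rice libraries: endosperm from 2 CF and 2 GM plants, and flag leaves in 3 CF and 3 GM replicates, all taken at day 5 after flowering. CF stands for chemical fertilizer and GM for hairy vetch green manure. The series asks, by its title, how green manure relates to heat resilience of the developing grain in this cultivar. No temperature is recorded for any sample. Endosperm libraries held 19173953 and 12200510 counted reads under CF and 20771235 and 18656783 under GM. Flag leaf libraries held 20247748, 18540688 and 25827356 under CF and 12960498, 12500336 and 15933394 under GM, so every GM leaf library was shallower than every CF leaf library. The first principal component took 44.1% of the variance in the endosperm and 35.0% in the leaf, and in each tissue it parted CF from GM libraries. P-values may measure only the spread between these samples, because the labels do not describe repeated plots.

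Tissue identity was plain in the counts. Under CF, 36 of 37 storage protein genes and 20 of 25 starch synthesis genes were higher in endosperm than in leaf. Photosystem and light-harvesting genes went the other way, with 53 of 56 higher in leaf. In all, 20803 of 25035 genes tested differed between the tissues, 11274 higher in endosperm and 9529 higher in leaf.

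In the endosperm, the question was which transcripts differ between grains fed by green manure and by chemical fertilizer. Heat shock genes were among the largest falls under GM. HSP101 (Os05g0519700), a chaperone of acquired thermotolerance, went from 275 ± 1.26 CPM under CF to 61.3 ± 0.693 CPM under GM (SD, n = 2 each), a log2 change of −2.17 (SE 0.11, adjusted p = 2.3e-06). The heat stress transcription factor HSfA2a (Os03g0745000) had a log2 change of −3.37 (SE 0.19, adjusted p = 3.9e-05), with means of 41.2 CPM under CF and 4.03 CPM under GM. Of 23094 genes tested, 292 were called, 285 lower and 7 higher under GM.

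Small heat shock proteins, which hold unfolding proteins in solution, fell with HSP101. OsHSP18.0-CIII (Os02g0782500) had a log2 change of −2.36 (SE 0.14), OsHSP18.0-CI (Os03g0267000) of −2.34 (SE 0.18) and HSP20 (Os06g0253100) of −2.29 (SE 0.13). Of 65 measured members of the heat shock protein list, 21 were lower and none higher, or 24 lower when adjusted over the list alone, and the median log2 change was −0.30. The list passed camera at adjusted p = 1.1e-11, and the call was lost at adjusted p = 0.310 with an estimated correlation. Of 22 heat stress transcription factors, 8 were lower and none higher, 11 lower when adjusted over the list alone, with a median of −0.48 and camera adjusted p = 5.4e-07 (adjusted p = 0.310 with an estimated correlation). OsHsfA6a (Os10g0419300) went from 167 ± 2.25 to 48.3 ± 9.35 CPM and HSFB2C (Os09g0526600) from 43.0 ± 1.22 to 16.4 ± 0.852 CPM. HSFB2B (Os08g0546800) had a log2 change of −2.34 (SE 0.27, adjusted p = 0.037), a call that was lost without CF replicate 1 or CF replicate 2 (adjusted p up to 0.494). The transcription factor list counted 4 calls without CF replicate 1 and 5 without CF replicate 2. The other 2 of the 8 largest falls under the naming rule were OsPUB63 (Os06g0159900), an arm repeat protein, at −2.30 (SE 0.15), and Os05g0296800, annotated as similar to a retrotransposon, at −2.26 (SE 0.20). Embryo and aleurone markers moved in the same direction, with a median log2 change of −0.72.

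**Figure D1:**
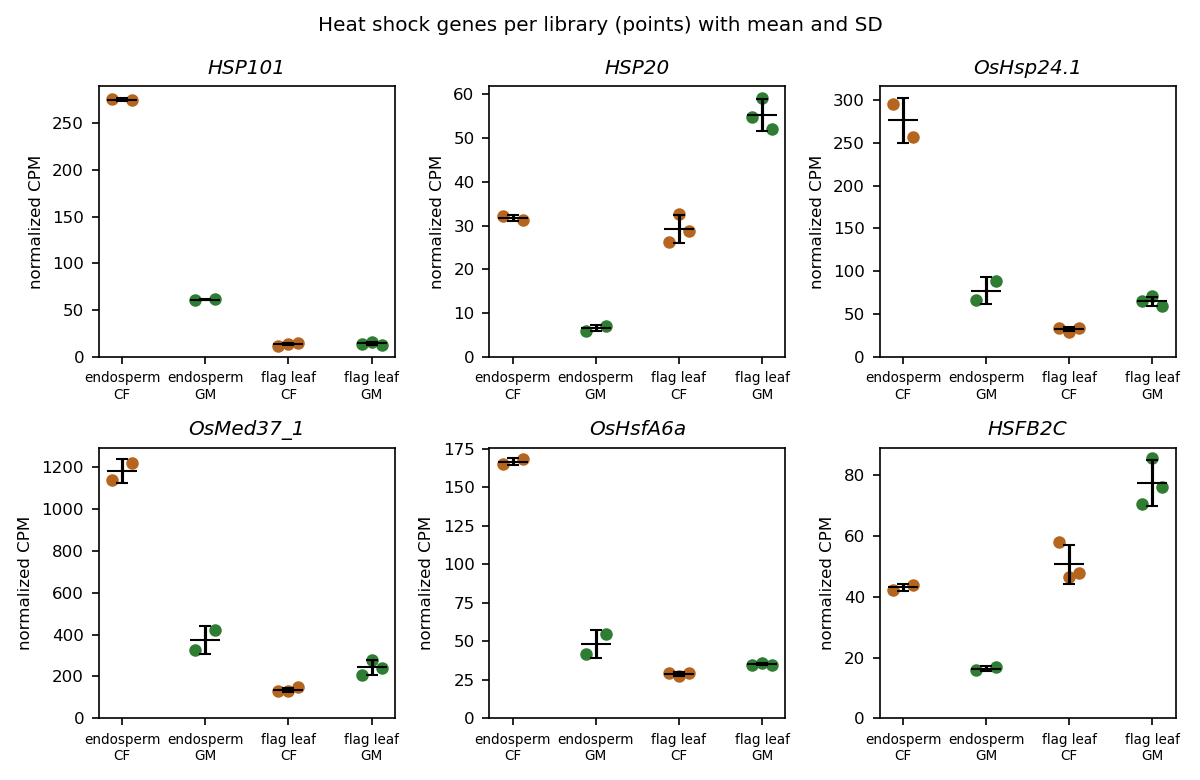
TMM-scaled CPM of 6 heat shock genes in each library, by tissue and fertilizer (CF brown, GM green; black bars, mean and SD; n = 2 per endosperm group and 3 per leaf group). In the endosperm, both GM libraries lie below both CF libraries for each gene, while HSP20 in the leaf has means of 29.2 under CF and 55.4 under GM.

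Late embryogenesis abundant (LEA) and oil body transcripts, typical of embryo, aleurone and drying seed, also fell in the GM endosperm. Of 38 members of the abscisic acid and LEA list, 9 were lower and none higher, 14 lower when adjusted over the list alone, with a median log2 change of −0.59 and camera adjusted p = 7.7e-08 (adjusted p = 0.348 with an estimated correlation). The median was −0.13 without CF replicate 1, and the count was 16 lower and 1 higher without GM replicate 2. OsLEA15 (Os02g0250600) had a log2 change of −2.07 (SE 0.22), OsLEA4 (Os08g0327700) of −1.40 (SE 0.14) and OsLEA3-1 (Os05g0542500) of −1.24 (SE 0.13). All 10 embryo and aleurone markers had negative values, and 4 of them were lower, 5 when adjusted over the list alone (camera adjusted p = 2.1e-06, and adjusted p = 0.310 with an estimated correlation). Among them, the peroxiredoxin Os1-CysPrxA (Os07g0638300) went from 227 ± 1.82 to 74.5 ± 6.81 CPM, and the oleosins OLE16 (Os04g0546500) and OLE18 (Os03g0699000) had log2 changes of −0.89 (SE 0.13) and −0.87 (SE 0.13). Markers of maternal pericarp and nucellus, 7 genes, had a median of −0.05 and no call (edgeR; 1 at an unadjusted p under 0.05).

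Starch synthesis genes showed no call in the endosperm by edgeR: 0 of 25, also 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05, with a median log2 change of −0.03 (camera adjusted p = 0.364). The granule-bound starch synthase WX1 (Os06g0133000) had a value of −0.37 (SE 0.20, adjusted p = 0.421), and the soluble synthase ALK (Os06g0229800) of −0.28 (SE 0.14, adjusted p = 0.368). Values were −0.03 for the branching enzyme SBE3 (SE 0.21), and 0.06 (SE 0.21) and −0.03 (SE 0.22) for the ADP-glucose pyrophosphorylase subunits AGPL2 and OsAGPS2a, and none was called. The alpha-amylase Amy3D had 0 reads in the CF and 2 reads in the GM endosperm libraries together, too few to test. The storage protein list did not take in every seed allergen gene, and further ones called lower are given under other observations. Storage protein genes had a median of −0.38 over 37 members, of which 2 were lower, also 2 when adjusted over the list alone (camera adjusted p = 0.00358, and adjusted p = 0.832 with an estimated correlation). Both are seed allergen genes: RA17 (Os07g0214100) at −1.10 (SE 0.17), and RA5B (Os07g0214600) at −0.75 (SE 0.14), whose call was lost without CF replicate 1 or CF replicate 2 (adjusted p up to 0.131). The storage list lost its call without CF replicate 1 or GM replicate 1 (adjusted p up to 0.986). Regulators of starch and storage protein genes, 9 in the list, had a median of −0.29, no call (edgeR; 1 lower when adjusted over the list alone, 3 at an unadjusted p under 0.05) and camera adjusted p = 0.0790.

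Photosystem and light-harvesting genes shifted down as a list in the endosperm, with a median log2 change of −0.35 over 54 members (camera adjusted p = 7.5e-06, and adjusted p = 0.775 with an estimated correlation). No member was called by edgeR over all genes, 11 were lower when adjusted over the list alone, and 27 had an unadjusted p under 0.05. Lhcb1.1 (Os01g0720500) had a value of −0.65 (SE 0.15, adjusted p = 0.083) and CAB2R (Os01g0600900) of −0.60 (SE 0.17, adjusted p = 0.136). Aquaporins shifted down with a median of −0.22 over 25 members, 1 of them lower and 4 lower when adjusted over the list alone (camera adjusted p = 0.00069, and adjusted p = 0.481 with an estimated correlation). That gene, the vacuolar channel OsTIP1_2 (Os03g0146100), had a log2 change of −0.58 (SE 0.12) and lost its call without CF replicate 1 (adjusted p = 0.308). Sugar transport and cleavage genes had a median of −0.13 over 68 members, 1 lower and 4 lower when adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.529 with an estimated correlation). The list was not called without CF replicate 1, CF replicate 2 or GM replicate 2 (adjusted p up to 0.401). The vacuolar invertase OSINV3 (Os02g0106100) was its called gene, at −0.62 (SE 0.10). Embryo and aleurone markers moved in the same direction as these 3 lists, with a median of −0.72.

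Dividing-cell genes shifted up in the GM endosperm. The cell cycle and DNA replication list, 68 genes, had a median log2 change of 0.20 (camera adjusted p = 4.5e-06, and adjusted p = 0.529 with an estimated correlation), with no single call by edgeR, none adjusted over the list alone and 22 genes at an unadjusted p under 0.05. OsMCM3 (Os05g0476200), a replication licensing factor, had a value of 0.42 (SE 0.10, adjusted p = 0.076). Cytosolic ribosomal proteins had a median of 0.11 over 141 genes, with no call by edgeR, none adjusted over the list alone and 17 at an unadjusted p under 0.05 (camera adjusted p = 6.3e-05, and adjusted p = 0.832 with an estimated correlation). That list was not called without CF replicate 2 or GM replicate 2 (adjusted p up to 0.707). ER chaperones and folding enzymes had a median of 0.18 over 21 genes and camera adjusted p = 0.0491 (adjusted p = 0.529 with an estimated correlation). They had no call by edgeR, none adjusted over the list alone and 4 at an unadjusted p under 0.05, and the list was not called without CF replicate 1, CF replicate 2 or GM replicate 2 (adjusted p up to 0.219).

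Nutrient genes moved little in the endosperm. Nitrogen uptake and assimilation genes had a median of 0.04 but a mean of −0.04 over 37 members, 1 of them lower and 2 when adjusted over the list alone (camera adjusted p = 0.806): the nitrate transporter OsNRT1.5A (Os02g0689900), at −1.07 (SE 0.22). Phosphate starvation genes had a median of −0.01 over 56 members, with 2 lower, also 2 when adjusted over the list alone (camera adjusted p = 0.551). These were the phosphate sensors OsSPX1 (Os06g0603600), at −0.66 (SE 0.13), and OsSPX2 (Os02g0202200), at −0.64 (SE 0.13). OsNRT1.5A lost its call without CF replicate 1 or CF replicate 2 (adjusted p up to 0.219), OsSPX1 without CF replicate 1 (adjusted p = 0.230) and OsSPX2 without CF replicate 1 or GM replicate 1 (adjusted p up to 0.243). Among lists past no test, the defence median of 0.43 rested on GM replicate 1: relative to CF, the mean over its 51 genes was 0.83 in GM replicate 1 and 0.06 in GM replicate 2. Without GM replicate 1 that median was 0.08, with 4 genes higher and 1 lower. It was 0.90 without CF replicate 1 and 0.67 without GM replicate 2, with 26 higher and 4 lower in the latter, and 22 were higher and 2 lower with no filter. The other medians were 0.11 for DNA methylation, 0.06 for the circadian clock, 0.04 for potassium transport, 0.03 for starch degradation and 0.00 for both reactive oxygen scavenging and auxin. They were −0.02 for sulfur, iron and zinc, −0.04 for chlorophyll breakdown, −0.09 for chlorophyll synthesis, −0.16 for fatty acids and wax (6 lower when adjusted over the list alone) and −0.18 for hypoxia. In these lists the beta-amylase OsBamy2 (Os03g0141200) was lower at −0.54 (SE 0.11) and the catalase CATC (Os03g0131200) at −0.62 (SE 0.11), with 2 and 1 lower when adjusted over their lists alone. OsBamy2 was not called without CF replicate 1, CF replicate 2 or GM replicate 2 (adjusted p up to 0.185), and CATC without CF replicate 1 (adjusted p = 0.143). Neither OsBamy2 nor CATC was called in the fit of both tissues together. Median, mean and test differed in sign for nitrogen, starch degradation, oxygen scavenging and the sulfur, iron and zinc list, and fry and camera did for potassium.

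Only 4 rises met the rule for named genes in the endosperm: OsSCAR2 (Os03g0298700) at 0.90 (SE 0.19, adjusted p = 0.048), OsWD40-182 (Os11g0134500) at 0.52 (SE 0.10, adjusted p = 0.031), OsFKBP58 (Os04g0446500) at 0.47 (SE 0.10, adjusted p = 0.038) and NOC3 (Os06g0498500) at 0.47 (SE 0.10, adjusted p = 0.042). None of these calls held in every smaller fit. OsSCAR2 and OsFKBP58 lost the call without CF replicate 1, CF replicate 2 or GM replicate 2 (adjusted p up to 0.220 each), OsWD40-182 without CF replicate 1 (adjusted p = 0.216) and NOC3 without CF replicate 1, CF replicate 2 or GM replicate 1 (adjusted p up to 0.129). All 292 called genes had values that did not overlap between CF and GM, as did 46.3% of all genes tested, against 33.3% by chance. The count of called genes was 135 without CF replicate 1, 694 without GM replicate 1 and 944 without GM replicate 2. It was 1370 with no expression filter and 49 in a test against a 1.5-fold change. The balance of directions moved too: 7 higher and 285 lower became 360 and 584 without GM replicate 2, 122 and 572 without GM replicate 1, 0 and 135 without CF replicate 1, 19 and 288 without CF replicate 2, and 368 and 1002 with no filter.

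In the flag leaf, the same contrast asks what the source leaf of the grain shows. Ribosomal protein, defence and heat shock transcripts rose under GM, and starch synthesis transcripts fell. Of 20208 genes tested, 594 were called, 499 higher and 95 lower, and changes were modest: 80 called genes reached 2-fold. Cytosolic ribosomal proteins, the parts of the protein-making machinery, had a median log2 change of 0.46, with 82 of 141 higher and none lower, 124 higher when adjusted over the list alone (camera adjusted p = 2.8e-40, and adjusted p = 0.385 with an estimated correlation). The L4 protein gene Os07g0180900 went from 120 ± 5.58 to 187 ± 23.4 CPM (SD, n = 3 each; log2 0.64, SE 0.09), and the L27a-3 gene Os07g0613200 from 23.2 ± 0.447 to 33.8 ± 1.51 CPM (log2 0.54, SE 0.08). The median stayed at 0.46 without CF replicate 2 and at 0.44 without CF replicate 3, but 0 and 1 of the 141 genes were called by edgeR in these smaller fits, 53 without CF replicate 1, 45 without GM replicate 2 and 52 in the fit with the endosperm libraries. Os07g0613200 lost its call without CF replicate 2 (adjusted p = 0.055) and Os07g0180900 without CF replicate 2 or CF replicate 3 (adjusted p up to 0.068).

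Defence genes had the largest median rise of the leaf lists. Of 44 pathogenesis-related and phytoalexin genes, 14 were higher and none lower, 24 higher when adjusted over the list alone, with a median of 0.85 (camera adjusted p = 3.2e-12, and adjusted p = 0.140 with an estimated correlation). Diterpenoid phytoalexin enzymes were the 3 largest rises under the naming rule, which asks for a mean of at least 5 CPM: OsCPS4 (Os04g0178300), a syn-copalyl diphosphate synthase, went from 15.3 ± 3.27 to 46.0 ± 10.2 CPM (log2 1.59, SE 0.19, adjusted p = 0.0092). OsKS7 (Os02g0570400), which makes the phytocassane precursor, had a log2 change of 1.46 (SE 0.29), and CYP99A2 (Os04g0180400) of 1.45 (SE 0.27). The chitinase Oschib1 (Os10g0416500) rose by 1.28 (SE 0.18), and the PR-10 proteins RSOsPR10 (Os12g0555000) and RPR10b (Os12g0555200) by 1.10 (SE 0.13) and 0.94 (SE 0.11) on the log2 scale. The other large rises were ASLRK (Os01g0742400) at 1.42 (SE 0.14), OsAGP22 (Os02g0718100) at 1.39 (SE 0.19), OsBDG1 (Os11g0514400) at 1.20 (SE 0.19) and the lignin enzyme 4CL5 (Os08g0448000) at 1.20 (SE 0.21). OsCPS4, ASLRK, OsAGP22, RSOsPR10 and RPR10b kept the call whichever library was left out. OsKS7 lost it without CF replicate 2, CF replicate 3 or GM replicate 1 (adjusted p up to 0.181), CYP99A2 without CF replicate 2, CF replicate 3 or GM replicate 2 (adjusted p up to 0.112) and 4CL5 without CF replicate 2 or GM replicate 3 (adjusted p up to 0.091). Oschib1 and OsBDG1 lost it without CF replicate 2 (adjusted p = 0.053 and 0.074). The list counted 5 calls without CF replicate 2, 8 without CF replicate 3 and 3 in the fit with the endosperm libraries. In that joint fit OsCPS4, RSOsPR10 and RPR10b were not called (adjusted p = 0.210, 0.365 and 0.329), nor were OsKS7, CYP99A2, Oschib1 and 4CL5.

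Heat shock transcripts rose in the leaf under GM, the opposite of the endosperm. Of 54 heat shock protein genes, 15 were higher and none lower, 23 higher when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 6.9e-09, and adjusted p = 0.140 with an estimated correlation). OsHsp24.1 (Os02g0758000), a mitochondrial small heat shock protein, rose to a mean of 64.9 ± 5.50 CPM (log2 1.02, SE 0.09), and HSP20 had a log2 change of 0.92 (SE 0.09). OsMed37_1 (Os01g0840100), an HSP70, rose by 0.84 (SE 0.11), a call lost without CF replicate 2 (adjusted p = 0.050). HSP101 had a value of 0.06 and was not called. Of 17 heat stress transcription factors, 6 were higher and none lower, with 8 higher and 1 lower when adjusted over the list alone, and a median of 0.29 (camera adjusted p = 0.00043, and adjusted p = 0.214 with an estimated correlation). HSFB2B rose by 0.83 (SE 0.09) and SPL7 (Os05g0530400) by 0.68 (SE 0.09), the latter not called without CF replicate 2 (adjusted p = 0.065). Without CF replicate 2, 2 heat shock proteins and 1 factor were called, and without CF replicate 3, 6 and 2. Leaving out CF replicate 1 gave 8 and 3, and the factors also counted 3 without GM replicate 2 or GM replicate 3 and in the fit with the endosperm libraries. ER chaperones rose in 7 of 20 genes, 11 when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 6.8e-07, and adjusted p = 0.218 with an estimated correlation). They include the disulfide isomerase ESP2 (Os11g0199200) at 0.55 (SE 0.07) and the chaperone OsBiP1 (Os02g0115900) at 0.60 (SE 0.08), the latter not called without CF replicate 2 (adjusted p = 0.068) and ESP2 not called in the joint fit (adjusted p = 0.054).

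**Figure D2:**
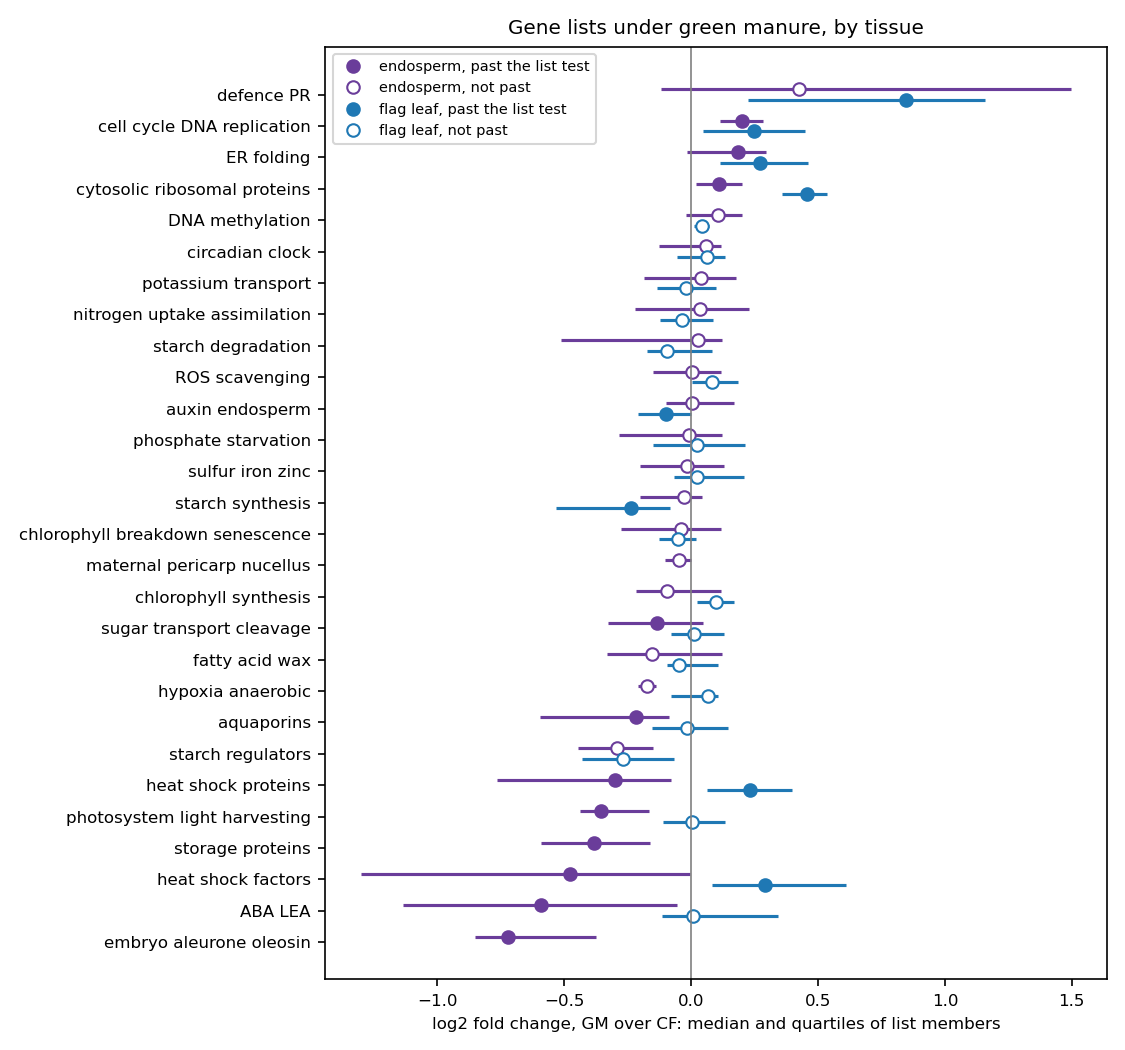
Median log2 fold change (GM over CF) of each gene list with at least 4 measured members, in endosperm (purple) and flag leaf (blue); lines span the quartiles of members and filled points passed camera at an adjusted p under 0.05. Heat stress transcription factors have medians of −0.48 in the endosperm and 0.29 in the leaf.

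Cell cycle and DNA replication genes rose as a list in the leaf. Of 43 cell cycle and DNA replication genes, 8 were higher and none lower, 18 higher when adjusted over the list alone, with a median of 0.25 (camera adjusted p = 6.3e-06, and adjusted p = 0.385 with an estimated correlation). The called members named by the rule are histones, which package DNA: OsH2A (Os07g0545300) at 0.75 (SE 0.08), the H3 gene Os06g0130900 at 0.70 (SE 0.09) and the H4 gene H4/Os09g0553100 at 0.65 (SE 0.09), the last not called without CF replicate 2 (adjusted p = 0.070). Starch synthesis genes fell, with 4 of 22 lower and none higher, 7 lower and 1 higher when adjusted over the list alone, and a median of −0.24 (camera adjusted p = 6.3e-06, and adjusted p = 0.423 with an estimated correlation). The branching enzymes SBE3 and OsBEIIa (Os04g0409200) had log2 changes of −0.54 (SE 0.09) and −0.53 (SE 0.09), and the plastidial phosphorylase Pho1_5 (Os03g0758100) of −0.48 (SE 0.09). SBE3 was not called without CF replicate 2, CF replicate 3 or GM replicate 3 (adjusted p up to 0.094), OsBEIIa without CF replicate 2 or CF replicate 3 (adjusted p up to 0.098), and Pho1_5 without either of these, GM replicate 2 or GM replicate 3 (adjusted p up to 0.112). Auxin genes shifted down slightly, with a median of −0.10 over 48 members and no call by edgeR, 3 lower when adjusted over the list alone and 10 at an unadjusted p under 0.05 (camera adjusted p = 0.00162, and adjusted p = 0.423 with an estimated correlation).

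The largest fall in the GM leaf under the naming rule was the vacuolar iron transporter family gene OsVIT2 (Os09g0396900), from 20.9 ± 1.21 to 9.05 ± 2.66 CPM (log2 −1.21, SE 0.16, adjusted p = 0.0069). The ferritins FER2 (Os12g0106000) and OsFER1 (Os11g0106700) had log2 changes of −0.72 (SE 0.13) and −0.68 (SE 0.14), while the sulfur, iron and zinc list as a whole had a median of 0.02 over 26 members, with 1 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.974). The annotation term for iron homeostasis held 2 of 8 genes among those lower (1-sided Fisher's exact test, adjusted p = 0.212). Other large falls were the beta-amylase BMY1 (Os07g0543100) at −0.83 (SE 0.19), Os11g0492300 at −0.82 (SE 0.17), Os09g0497100 at −0.75 (SE 0.18), the transcription factor OsbZIP88 (Os12g0601800) at −0.74 (SE 0.09), Os08g0208700 at −0.73 (SE 0.17) and FWL4 (Os03g0830400) at −0.69 (SE 0.16). Of these falls, OsbZIP88 kept its call whichever library was left out. OsVIT2 lost it without CF replicate 2 (adjusted p = 0.053), FER2 and Os11g0492300 without CF replicate 2, CF replicate 3 or GM replicate 2 (adjusted p up to 0.111 and 0.148). OsFER1 lost it without any CF replicate or GM replicate 2 (adjusted p up to 0.129), BMY1 without CF replicate 2, CF replicate 3, GM replicate 1 or GM replicate 2 (up to 0.152), and Os09g0497100 without CF replicate 2, CF replicate 3, GM replicate 2 or GM replicate 3 (up to 0.210). Os08g0208700 lost it without CF replicate 1, CF replicate 2, GM replicate 1 or GM replicate 3 (adjusted p up to 0.168), and FWL4 without any library but CF replicate 1 (up to 0.159).

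Nutrient lists did not pass in the leaf. Nitrogen uptake and assimilation genes had a median of −0.03 but a mean of 0.07 over 39 members, with 2 higher, also 2 when adjusted over the list alone (camera adjusted p = 0.974), among them the glutamate synthase OsGLT2 (Os05g0555600) at 1.04 (SE 0.19), not called without CF replicate 3, GM replicate 2 or GM replicate 3 (adjusted p up to 0.129). Phosphate starvation genes had a median of 0.02 over 48 members, with 2 higher and 1 lower, 3 and 3 when adjusted over the list alone (camera adjusted p = 0.977). The phosphate transporter PT8 (Os10g0444700) rose by 0.39 (SE 0.09), the transporter trafficking protein PHF1 (Os07g0187700) by 0.41 (SE 0.10), and the acid phosphatase OsPAP9b (Os01g0800500) had a log2 change of −0.47 (SE 0.10). OsPAP9b and PT8 were not called without any of the CF replicates or GM replicate 2 (adjusted p up to 0.113 and 0.192), and PHF1 without any library but GM replicate 1 (adjusted p up to 0.205). Photosystem genes had a median of 0.00, no call by edgeR, none adjusted over the list alone and 6 at an unadjusted p under 0.05 (55 genes, camera adjusted p = 0.974). Medians of other lists past no test were 0.10 for chlorophyll synthesis, 0.08 for oxygen scavenging, 0.07 for hypoxia, 0.06 for the clock, 0.04 for DNA methylation, and 0.01 for both sugar transport and the abscisic acid and LEA list. They were −0.01 for aquaporins, −0.02 for potassium, −0.05 for both chlorophyll breakdown and wax, −0.09 for starch degradation and −0.27 for starch regulators. Called members of these lists were 2 lower starch regulators of 4, 1 higher and 1 lower gene each in starch degradation and aquaporins, 1 higher in sugar transport and in wax, 1 lower in the clock, and 2 higher and 1 lower in the abscisic acid and LEA list. When adjusted over the list alone, these counts were the same but for sugar transport with 0 and aquaporins with 2 higher. Among these genes, OsLEA9 (Os01g0314800) rose by 0.91 (SE 0.12) and kept its call whichever leaf library was left out, but not in the joint fit, while flo4 (Os05g0405000) at −0.44 (SE 0.09) lost it without CF replicate 2, CF replicate 3 or GM replicate 3 (adjusted p up to 0.174) and in the joint fit, and RSR1 (Os05g0121600) at −0.43 (SE 0.10) without any of these libraries or GM replicate 2 (up to 0.184) and at equal depth. Median, mean and test differed in sign for nitrogen, photosystem, aquaporins, clock, wax and hypoxia. Storage proteins, embryo and aleurone markers and maternal markers had too few leaf members to test, with medians of −0.06, 0.02 and 0.17.

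All 594 genes called in the leaf had values that did not overlap between CF and GM, as did 22.3% of all genes tested, against 10% by chance. The count of called genes was 40 without CF replicate 2, 70 without CF replicate 3, 933 without GM replicate 1 and 313 without GM replicate 2. It was 378 in a fit with the endosperm libraries, 987 with no expression filter and 0 in edgeR's test against a 1.5-fold change, where 309 genes had an unadjusted p under 0.05 and no other tool was run. Of the directions, 499 higher and 95 lower became 729 and 204 without GM replicate 1, 262 and 51 without GM replicate 2, 358 and 40 without GM replicate 3, 35 and 5 without CF replicate 2, 63 and 7 without CF replicate 3, and 372 and 78 without CF replicate 1. They were 299 and 79 in the joint fit, 621 and 159 with DESeq2, and 776 and 211 with no filter.

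The interaction asked whether the GM effect differed between endosperm and leaf, and heat shock genes were among those with the largest differences. Of 25035 genes tested, 154 were called, 139 with a more negative effect in the endosperm and 15 with a more positive one, and 88 of them were lower in the endosperm with a positive leaf value. Heat shock protein and factor lists held 21 and 6 of the called genes. HSP20 differed by −3.18 (SE 0.16, adjusted p = 1.1e-07) and HSFB2B by −3.15 (SE 0.23, adjusted p = 5.2e-06). Os05g0296800 differed by −3.24 (SE 0.38, adjusted p = 0.00035). HSfA2a differed by −3.87 (SE 0.61, adjusted p = 0.0056), with 14 CF and 13 GM reads over 3 leaf libraries each. The cytochrome P450 gene CYP72A1 (Os01g0627800) differed by −2.88 (SE 0.50, adjusted p = 0.012), with 26 CF and 5 GM reads in the endosperm, and lost its call without endosperm CF replicate 1, GM replicate 1 or GM replicate 2 (adjusted p up to 0.230).

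Of 69 heat shock proteins and factors measured in both tissues, 26 were lower in the endosperm, 21 were higher in the leaf and 14 were both, and the GM effect differed between tissues for 26. Across all 18494 genes tested in both, 30 were lower in endosperm and higher in leaf, against 5.04 expected (Fisher's exact test, 2-sided, p = 3.6e-15), while 2 were lower in both against 0.922 expected (p = 0.235) and 2, OsFKBP58 and OsWD40-182, higher in both against 0.145 expected (p = 0.0082). In the interaction, the heat shock protein list had a median of −0.40 with 21 of 67 genes called, 30 when adjusted over the list alone, and the factor list −0.50 with 6 of 23, or 8 (adjusted p = 0.0112 for each with an estimated correlation). The abscisic acid and LEA list and the embryo and aleurone markers also held (adjusted p = 0.0424 for each with an estimated correlation), with medians of −0.57 and −0.73. They had no called gene by edgeR, none adjusted over the list alone, and 9 and 0 genes at an unadjusted p under 0.05. Of their genes, 15 and 1 passed the filter in both tissues, with medians of −0.08 and −0.02 over these, so most of their genes are scarcely read in leaf. The LEA median was −0.14 without endosperm CF replicate 1, and the marker median −0.37 without leaf GM replicate 3. Starch synthesis (0.21), auxin (0.16), photosystem (−0.33), aquaporin (−0.27) and ribosomal (−0.30) lists passed camera but not with an estimated correlation (adjusted p = 0.809, 0.674, 0.810, 0.514 and 0.810 with an estimated correlation). None had a called gene by edgeR, and 7, 13, 14, 6 and 41 had an unadjusted p under 0.05. When adjusted over the list alone, 3 starch synthesis genes were positive, and 1 aquaporin was positive and 3 negative. Median, mean and test differed in sign for the ER, nitrogen, defence, clock and DNA methylation lists.

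**Figure D3:**
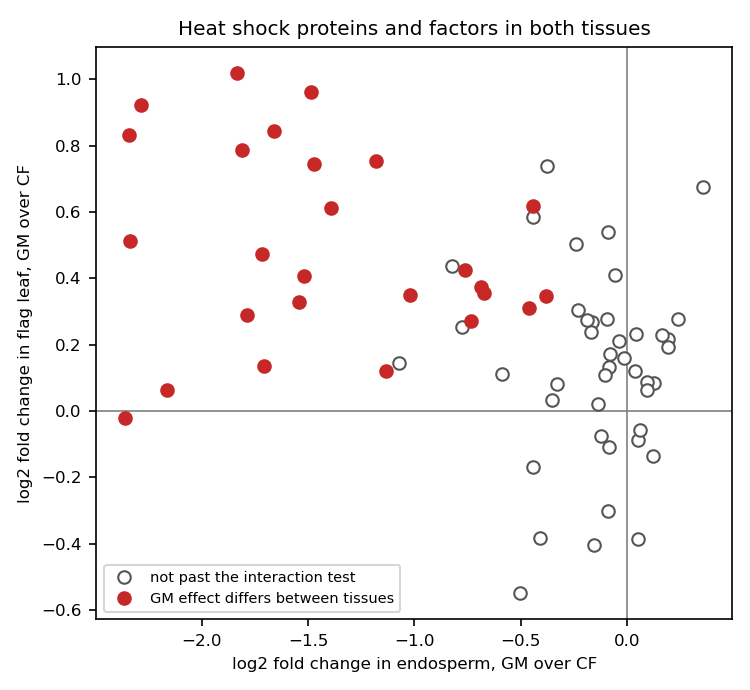
Log2 fold change (GM over CF) of 69 heat shock proteins and transcription factors in endosperm (horizontal axis) and flag leaf (vertical axis); red points have a GM effect that differed between tissues at an adjusted p under 0.05. Of the 26 genes lower in the endosperm, 24 have a positive leaf value.

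Positive differences were fewer, and their count moved with the libraries: 15 became 77 without endosperm GM replicate 2, 38 without leaf GM replicate 1, 3 without endosperm CF replicate 1 or leaf CF replicate 3, 5 without endosperm CF replicate 2, 7 without leaf CF replicate 2, 9 without leaf GM replicate 3, 56 with DESeq2 and 7 with limma-voom and quality weights. CCA1 (Os08g0157600), a morning gene of the circadian clock, differed by 0.79 (SE 0.16, adjusted p = 0.037), with a leaf change of −0.42, called in 1 of 6 smaller leaf fits (adjusted p up to 0.183), and an endosperm value of 0.34. Os12g0484600 differed by 1.94 (SE 0.38), with 20 CF and 82 GM reads in the endosperm libraries together. Os02g0734400 differed by 1.88 (SE 0.35), with 134 CF and 28 GM reads in the leaf libraries together. OsSCAR2 differed by 0.93 (SE 0.20) and Fbox-14 (Os11g0205800) by 0.89 (SE 0.18). With limma-voom and quality weights, these 4 genes and CYP72A1 were not called (adjusted p up to 0.183). OsSCAR2 lost its call whichever library was left out (adjusted p up to 0.242). CCA1 lost it without 7 of the 10 libraries (adjusted p up to 0.138): endosperm CF replicate 1, CF replicate 2 and GM replicate 1, the CF leaf replicates, and leaf GM replicate 3. Os12g0484600 lost it without endosperm CF replicate 1, CF replicate 2, GM replicate 1 or leaf CF replicate 2 (adjusted p up to 0.191), Os02g0734400 without endosperm CF replicate 1 or leaf GM replicate 3 (up to 0.090), and Fbox-14 without endosperm CF replicate 2, GM replicate 1, leaf CF replicate 2 or leaf CF replicate 3 (up to 0.146). The count of 154 was 80 without endosperm CF replicate 1, 88 without leaf CF replicate 2 and 100 without leaf GM replicate 3, and 352 with DESeq2.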

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

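The tests of embryo or aleurone share, of abundant genes, of stage, of depth and of library scaling below were chosen only after the results were seen, and those of short transcripts and leaf groupings before. The first of these compared heat shock genes with the median of the markers, which spoke against it; it was then made stricter, with the marker that fell most. The test of abundant genes replaced 3 earlier forms: a setting that moved almost nothing, one run only on genes called lower, and one that set the median against the SD over single members and left the question open. The test of library scaling replaced one planned before, in which other scalings shifted leaf genes by a median of at most 0.02 in size and so decided nothing.

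The GM effect differed between endosperm and leaf for 154 genes, by a test of the difference itself, which brought up every result in this part. Named heat shock genes had differences of −3.87 for HSfA2a, −3.18 for HSP20, −3.15 for HSFB2B, OsHsp24.1 −2.82, OsHSP18.0-CI −2.81, OsMed37_1 −2.47, OsHSP18.0-CIII −2.31, HSP101 −2.20, OsHsfA6a −2.05 and HSFB2C −1.97. List medians of the difference were −0.40 for heat shock proteins and −0.50 for heat stress transcription factors. Other genes were Os05g0296800, similar to a retrotransposon, at −3.24, CYP72A1 −2.88, OsPUB63 −2.76, H4/Os09g0553100 −0.90, OsBiP1 −0.81, Os12g0484600 1.94, Os02g0734400 1.88, OsSCAR2 0.93, Fbox-14 0.89 and CCA1 0.79. Further list medians were −0.73 for embryo and aleurone markers, −0.57 for abscisic acid and LEA genes, −0.33 for photosystem genes, −0.30 for ribosomal proteins, −0.27 for aquaporins, 0.21 for starch synthesis and 0.16 for auxin; the last 5 of these were not called with an estimated correlation (adjusted p = 0.514 to 0.810).

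For the lower heat shock transcripts in the GM endosperm, a few abundant genes taking counts would move all genes of a library alike. Such a shift cannot by itself set some genes apart from the rest. The median of all measured heat shock proteins and factors lay −0.38 from that of all genes. Relative to CF, the heat shock protein list mean was −0.53 in each GM endosperm library. These lists had already passed camera, so the distance was known before this test and adds no separate support. The SE of their median (0.0942) treats genes as independent and does not measure the spread between libraries. A smaller share of embryo or aleurone tissue in the GM samples stays open: the called heat shock genes had a median of −1.52, and the marker that fell most, Os1-CysPrxA, −1.61 (SE 0.11). An earlier stage of the GM endosperm also stays open, with a starch synthesis median of −0.0292 (SD over members 0.175). Beside it, the storage protein median was −0.38, with library means that overlapped between CF and GM. Fertilizer itself is a further open explanation that was not tested apart from tissue share and stage. No temperature record is at hand to set against a cooler grain.

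For the lower LEA and oleosin transcripts in the GM endosperm, the direction goes with a smaller share of embryo or aleurone tissue, since the highest marker had a log2 change of −0.513 times its SE and none rose. The spread over markers goes against a single factor (SD 0.434, with Os1-CysPrxA at −1.61 and OLE16 at −0.89, SE 0.13), unless the endosperm also makes some of them, which was not tested. Relative to the CF mean, the storage protein list stood at 0.40 and −0.40 in the CF and −0.62 and 0.03 in the GM endosperm libraries, which overlap. An earlier stage is not told apart from a smaller tissue share, with a storage protein median of −0.38 and a cell cycle median of 0.20. Both stay open: all samples share day 5 after flowering, but neither a finer stage nor how cleanly each endosperm was dissected is recorded. An effect of fertilizer also stays open and was not tested apart.

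For the higher ribosomal protein transcripts in the GM leaf, shallower GM libraries stay open: with all libraries thinned to equal depth the median log2 change was 0.46. Random thinning keeps the expected ratio of well-read genes, so this value was largely set beforehand. It cannot decide about library differences that go with depth. Library scaling moves all genes of a library alike, so it cannot by itself set the list 0.46 from the median of all genes. The list had already passed camera, so this distance was known beforehand and adds no separate support. Relative to CF, the list mean was 0.58, 0.40 and 0.25 in GM replicates 1, 2 and 3. The SE of the list median (0.0113) comes from resampling genes as if independent. It does not measure the spread between libraries. A gain of short transcripts of any kind is argued against as the whole cause, since plastid and mitochondrial ribosomal proteins had a median of 0.15. The SE of that median (0.03) is likewise over genes, not libraries. Transcript lengths are not given, and these genes stand in for them. An effect of fertilizer, plot or leaf stage stays open and was not tested.

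Of the 10 ways to split the 6 leaf libraries 3 against 3, 1 gave as many called genes as the real grouping (594), and the highest other gave 0. For gene lists, 1 of 10 gave as many as the real grouping (8), and every other split passed 3 to 6 lists while calling 0 genes. Each mixed grouping keeps unequal numbers of CF and GM libraries in its arms, so part of a GM effect stays in the comparison. Treatment also adds to the spread within its arms, which makes gene calls harder. The splits therefore cannot tell whether camera passes lists too easily. Its p-values at the preset correlation of 0.01 may still overstate the evidence, since the estimated correlation was 0.64 for the leaf ribosomal list. A set of 10 splits cannot give a share under 0.05.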

How the results depend on the processing

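The equal-depth setting for the leaf was chosen only after the results were seen; all other settings here were planned. Counts of called genes stayed within 1.5 times under other scalings, a stricter filter, limma-voom and abundant genes left out in each tissue: 236 to 351 for the endosperm (292) and 501 to 596 for the leaf (594), with 570 at equal depth. In the endosperm, 1370 genes were called with no filter and 49 against a 1.5-fold change, and leaving out a library gave 135 to 944. In the leaf, 987 were called with no filter, 378 in the joint fit and 0 against a 1.5-fold change, and leaving out a library gave 40 to 933. The difference between tissues was called for 352 genes with DESeq2, against 154, and for 80 to 204 with a library left out. The fold test asks for a larger change by construction; for all other moves, among them the rises with a library left out, the cause was not tested. Leaving out an endosperm library leaves 1 in an arm, which is assumed to vary like the others.

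Gene lists past the test went from 11 to 0 with an estimated correlation and 3 with fry in the endosperm, and from 8 to 0 and 5 in the leaf. Fry kept both heat shock lists in each tissue. It also kept the embryo and aleurone markers in the endosperm, and the ER, defence and cell cycle lists in the leaf. In the leaf, the ribosomal, starch synthesis and auxin lists did not pass fry (adjusted p = 0.0527, 0.0787 and 0.245). With estimated correlation, 4 lists in each tissue had an unadjusted p under 0.05 (camera). With a library left out, 8 to 11 lists passed in the endosperm and 8 to 9 in the leaf. With the replicate number as a block, 168 endosperm genes, 713 leaf genes and 67 differences between tissues were called, 3 of the differences positive. Of the named genes described below, 9 of the 27, 1 of the 41 and 5 of the 10 were not called. Of genes named outside them, 6 of 9 in the endosperm were not called, nor were RSR1, ROPGEF6, YK11 and ANTH3 in the leaf. The ER list had a camera adjusted p of 0.0540 in the endosperm. Deviations of same-numbered samples had correlations of −0.00822 in the endosperm and 0.0403, 0.0108 and −0.0108 in the leaf. CF leaf replicates 1 and 2 correlated best with their own number, and CF leaf replicate 3 with GM replicate 2 (0.0513). With 2 endosperm libraries per arm, same-numbered and other-numbered values differ only in sign. The check shows no clear pairing by number but cannot exclude it.

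Values that changed sign belonged to genes that were not called: SBE3 ranged from −0.19 to 0.12, AGPL2 from −0.20 to 0.27 and OsAGPS2a from −0.39 to 0.26 in the endosperm with a library left out, and the cause was not tested. Of the called genes that the naming rule gives for the described lists and the largest changes, 17 of 27 in the endosperm, 12 of 41 in the leaf and 4 of 10 between tissues kept the call in every smaller fit. Of the 27, 5 lost it with DESeq2 (OsSCAR2, NOC3, OsNRT1.5A, OsSPX1 and OsSPX2), 4 in the joint fit (OsFKBP58, NOC3, OSINV3 and OsNRT1.5A), 4 with upper-quartile factors, 3 with limma-voom and 14 against a 1.5-fold change. Of the 41, 15 lost it in the joint fit and 41 against a 1.5-fold change, with at most 3 under any other setting. Of the 10, 5 lost it with limma-voom and quality weights and 1 with RLE factors. Depth limits genes with few reads, such as HSfA2a in the leaf, with 14 CF and 13 GM reads.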

Other observations

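All tests of annotation terms here, and the genes picked from them, were chosen only after the results were seen; term tests are 1-sided Fisher's exact tests, adjusted over the terms tested. A family of seed allergen genes fell in the GM endosperm. These are small trypsin and alpha-amylase inhibitor-like storage proteins, and 6 of 8 measured were lower, against 0.0987 expected (adjusted p = 5.0e-08). RAG2 (Os07g0214300) went from 1697 ± 244 to 917 ± 142 CPM (log2 −0.89, SE 0.18), Os07g0216700 from 881 ± 33.4 to 487 ± 34.0 CPM (log2 −0.85, SE 0.14), and OsEnS-96 (Os07g0213800) and OsEnS-101 (Os07g0222000) had log2 changes of −0.86 (SE 0.16) and −0.59 (SE 0.11). RA5B and RA17 are the other 2, and the only ones of the 6 in the storage protein list. LTPL163 (Os07g0216600) at −0.99 and RA16 (Os07g0215500) at −0.54 were not called. Without CF replicate 1 or CF replicate 2, RAG2 and Os07g0216700 were not called either (adjusted p up to 0.156 and 0.066), nor was OsEnS-96 without CF replicate 2 (0.117) or OsEnS-101 without these or GM replicate 1 (up to 0.146). OsEnS-101 also lost its call in the joint fit. J-domain proteins, partners of HSP70, were lower in 9 of 82 genes, against 1.01 expected (adjusted p = 0.00012), among them OsDjC53 (Os06g0195800) at −1.93 (SE 0.18), OsDjB7 (Os05g0562300) at −1.52 (SE 0.14) and OsDjA5 (Os03g0787300), from 711 ± 3.00 to 375 ± 30.8 CPM. Embryo and aleurone markers fell beside both groups, with a median of −0.72.

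In the GM leaf, WRKY transcription factors, regulators of defence, were higher in 12 of 55 genes, against 1.64 expected (adjusted p = 1.3e-05). OsWRKY19 (Os05g0571200) had a log2 change of 1.66 (SE 0.19), WRKY28 (Os06g0649000) of 1.52 (SE 0.20), OsWRKY24 (Os01g0826400) of 1.01 (SE 0.10) and WRKY53 (Os05g0343400) of 0.44 (SE 0.08). The translation machinery rose beyond ribosomal proteins: 8 of 18 genes of initiation factor eIF3, against 0.604 expected (adjusted p = 3.0e-06), and 8 of 20 elongation factor genes, against 0.671 (adjusted p = 7.1e-06), were higher, with rfa3 (Os03g0177900) at 0.46 (SE 0.09). Calreticulin and calnexin genes, which fold proteins in the ER, were higher in 4 of 5, against 0.149 expected (adjusted p = 0.00051). WRKY53 and rfa3 were not called without CF replicate 2 or CF replicate 3 (adjusted p up to 0.113 and 0.161), and none of these WRKY genes nor rfa3 was called in the joint fit. No term passed among the genes lower in the leaf. Larger fold rises in the leaf stood at low levels, below the 5 CPM of the naming rule. Of these, 4 were chosen after their values were seen: DPF (Os01g0196300), a regulator of diterpenoid phytoalexins, at 2.11 (SE 0.26), ROPGEF6 (Os01g0675000) at 2.95 (SE 0.58, 0.207 to 1.84 CPM), YK11 (Os05g0280700) at 3.04 (SE 0.71) and ANTH3 (Os02g0175700) at 1.81 (SE 0.42). DPF kept its call whichever library was left out; ROPGEF6 lost it without CF replicate 2 or GM replicate 2 (adjusted p up to 0.118), YK11 whichever library was left out (up to 0.165) and ANTH3 without any but GM replicate 3 (up to 0.148). YK11 also lost it with RLE or upper-quartile factors and in the joint fit, and ANTH3 with limma-voom, in the joint fit and at equal depth.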
